A study of Arabidopsis thaliana with 24 samples.

How the data were processed

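The 24 libraries cover total RNA, NAD-captured RNA and GMUCT (uncapped and cleaved RNA) of Col-0 and dxo1 plants without hormone and with ABA, with 2 replicates in each of 12 groups. The deposited files hold counts, that is whole numbers of reads per gene, without normalization. Per the labels, the authors trimmed adapters with cutadapt, aligned reads with STAR 2.4.2a and counted them with HTSeq on the TAIR10 build, from strand-specific single-end reads of 50 nt. The versions of cutadapt and HTSeq, the counting mode and the annotation release are not given in the sources used here. Gene names and classes came from a TAIR10.1 annotation table that matched 28009 of 28775 gene identifiers (97.3%).

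Each of 4 sets of libraries was fitted in edgeR 4.0.16 under R 4.3.3: total RNA, NAD with total RNA, GMUCT with total RNA, and GMUCT alone. Genes passed filterByExpr with a minimum count of 10, libraries were scaled by TMM, and quasi-likelihood F tests were adjusted by the Benjamini-Hochberg method at 0.05. Errors of log2 fold changes, given as SE, are the absolute log2 fold change over the square root of its F statistic. They derive from the test of no change and are approximate, above all where a group has few counts. Labels of the 12 groups served as the only terms. A change of NAD enrichment is the log2 change in NAD libraries minus that in total RNA, and GMUCT over total RNA was treated alike. p-values measure the spread between samples labelled as replicates, which may be technical.

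The 21 gene lists were written before the data were examined: ABA-induced genes, clade A phosphatases, PYR/PYL receptors, ABA synthesis and catabolism, light harvesting and RBCS, nuclear photosystem subunits, chlorophyll synthesis, plastid transcription, mRNA decay, small RNA pathway, salicylate and defence, jasmonate, flavonoid and anthocyanin, heat shock, cell cycle, seed storage, floral organ, root, reference genes, and the chloroplast and mitochondrial genomes. Lists with at least 3 tested members were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, with a preset correlation of 0.01 and again with an estimated correlation. List adjusted p are adjusted over the lists of one comparison. The 19 planned comparisons, 4 planned correlations, the alternatives and the rule for naming genes were also fixed before the data were examined. The 5 comparisons of GMUCT libraries alone and 1 correlation were added after the depths were seen.

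Genes were named by rule. In 7 main comparisons these were the 6 largest positive and negative changes with a mean of at least 5 CPM among genes that passed, and up to 3 genes per list by smallest p. In the others they were the 2 largest each way and 1 per list. DXO1, RD29A, RD29B, RAB18, COR15A, HAI1, LHCB2.3, RBCS1A and PR1 could always be named, and where nothing passed the genes with the smallest p were named as such. Of the genes meeting the rule, some with few counts in a group of a double ratio were left out, and not every gene meeting it is printed.

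A fold against a group at 0 counts is a bound against a floor of 3 counts over the group. With 1 to 3 counts the ratio is given with a 95% exact counting interval. Floors and intervals cover counting error only. Alternatives were DESeq2 size factors, library size alone, the DESeq2 1.42.0 Wald test, no low-count filter, a mean of at least 10 CPM, removal of organelle genes, TMM within each assay, a replicate block, a fit of the groups in the contrast alone, leaving out each library in turn and, added after the data were seen, nuclear protein-coding genes alone. The fits were tested on data simulated with known changes. No mock capture was analysed here, and groups of 2 do not allow regrouping of samples or a test for outlying samples.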

Results

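The series measured RNA of Arabidopsis thaliana in 24 libraries that fall into 12 groups of 2 replicates. Plants were wild type Col-0 or the mutant dxo1, which carries a lesion in DXO1, an enzyme known to remove NAD caps from RNA. Each genotype was grown without hormone (NT) or with abscisic acid (ABA), the plant hormone of drought and seed maturation, at a dose that the labels do not give. Every combination was sequenced in 3 ways. Total RNA libraries gave the reference level of each transcript. NAD libraries were made from RNA captured through a 5' NAD cap, and GMUCT libraries from uncapped and cleaved transcripts, which carry a free 5' phosphate. The labels give an age of 12 days and name both seedlings and bud tissue, so the tissue was not settled here.

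Depth differed strongly between the assays. GMUCT libraries held 5.79 to 13.9 M (mega) counts in genes, with a mean of 9.89 ± 3.07 M (SD, n = 8). NAD libraries held 0.751 to 1.53 M and total RNA libraries 0.878 to 2.03 M. Protein-coding genes took 95.7% to 96.7% of the GMUCT counts, but 2.17% to 17.7% of the NAD counts and 12.7% to 26.3% of the total RNA counts. The mitochondrial gene ATMG01390 took 43.9% to 85.1% of counts in each NAD library. In total RNA the chloroplast gene ATCG00230 took 5.05% to 53.7%. The snoRNA share of total RNA was 9.89% ± 1.85 in Col-0 NT, 24.6% ± 0.407 in Col-0 ABA, 3.87% ± 3.85 in dxo1 NT and 45.2% ± 15.4 in dxo1 ABA (SD, n = 2). Of this, the single gene AT3G21805 took 2.88% ± 0.482, 12.0% ± 0.0328, 1.74% ± 2.19 and 36.0% ± 18.5 of the counts in the same order. Col-0 ABA NAD replicate 1 stood apart. Of the 1411 genes with at least 10 counts in all 7 other NAD libraries, 786 (55.7%) stayed below 10 in it. Replicates correlated across genes at r = 0.982 to 0.993 for GMUCT, 0.819 to 0.929 for NAD and 0.843 to 0.956 for total RNA, and genes are not independent replicates.

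**Figure D1:**
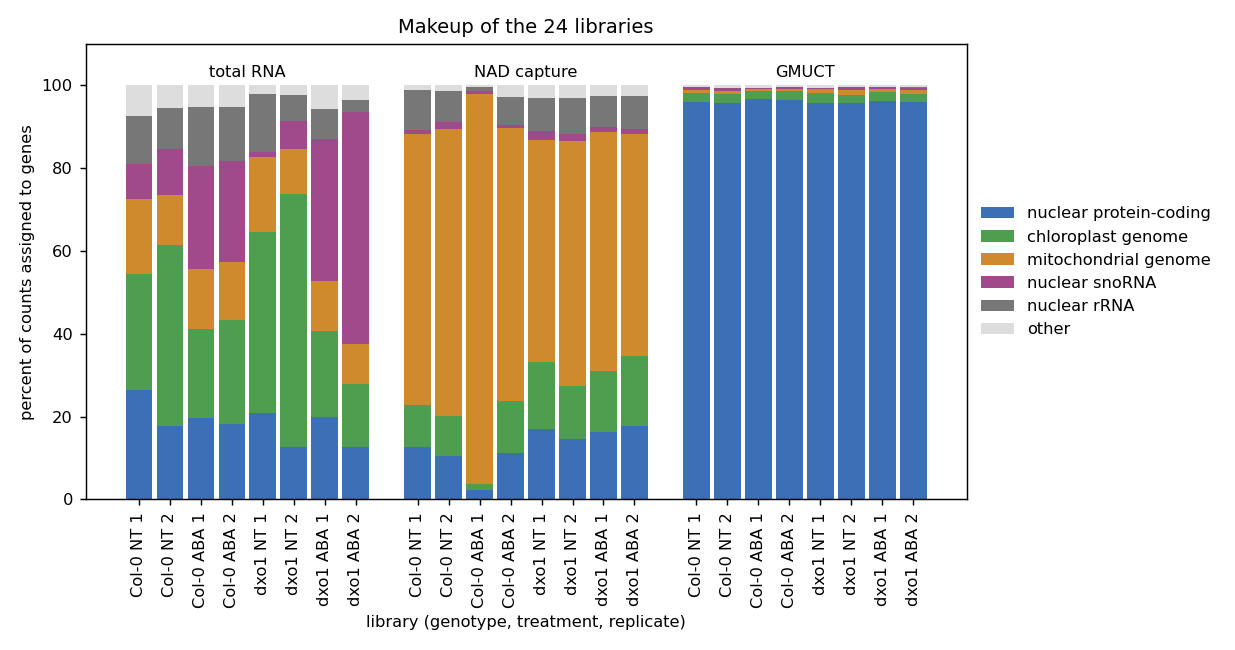
Share of gene counts (percent) taken by each class of gene in the 24 libraries, grouped by assay, with one bar per library. Mitochondrial genes took 53.6% to 94.0% of the NAD libraries.

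DXO1, the targeted gene, kept reads in every library. In GMUCT libraries its level was 27.1 ± 3.48 CPM (read counts scaled to an equal library total) in Col-0 NT, 27.9 ± 1.36 in Col-0 ABA, 21.4 ± 2.36 in dxo1 NT and 18.5 ± 2.12 in dxo1 ABA (SD, n = 2). DXO1 fell in dxo1 by 0.50 ± 0.17 on the log2 scale in NT (adjusted p = 0.0439) and by 0.87 ± 0.18 in ABA (adjusted p = 0.00133). The NT call was lost without any 1 of the 4 libraries, with library-size scaling and with the DESeq2 Wald test. Total RNA libraries held 1 to 8 reads of DXO1 and NAD libraries 1 to 6, too few for a comparison. Counts over the whole gene do not show whether a working transcript remained.

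The first comparison asked which transcripts ABA changed in total RNA of Col-0. Transcripts of late seed development rose from 0 counts in both NT libraries. AT3G02480, a gene of the late embryogenesis abundant (LEA) family, was at least 63.6-fold higher with ABA, CRU1 at least 51.8-fold and CRU3 at least 49.1-fold, the last 2 encoding cruciferin storage proteins. OLEO2, an oil-body oleosin, was at least 16.0-fold higher, and M17 at least 21.9-fold. RD29B and LEA4-5, both desiccation proteins, had 66 counts each with ABA and the glucosidase BGLU19 had 65, each against 0 in NT (bounds use a floor of 3 counts over the group at 0). The dehydrin RAB18 rose by a log2 fold change of 4.94 ± 0.57 (SE, n = 2, adjusted p = 0.000484). SEN1, a dark-induced gene, fell by 2.26 ± 0.41 on the log2 scale (adjusted p = 0.0231), AT2G33830 by 2.17 ± 0.37 (adjusted p = 0.0133) and the galactosidase BGAL4 by 2.11 ± 0.38 (adjusted p = 0.0231). RD29A stood at 1.47 ± 0.42 (adjusted p = 0.185) and LHCB2.3, a light-harvesting protein, at 1.06 ± 0.34 (adjusted p = 0.239), and neither passed the test.

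Of 4965 genes tested, 18 were higher and 4 lower. The ABA-induced list had 3 of 13 members higher, and 7 higher and 1 lower adjusted over the list alone (list median 1.28, camera adjusted p = 2.15e-07, adjusted p = 0.0332 with an estimated correlation). All 4 tested members of the seed storage list were higher adjusted over the list alone and 3 over all genes. Its median was 8.82 on fitted values and 4.81 with these members at their bound (adjusted p = 7.5e-13, adjusted p = 0.0248 with an estimated correlation). The PYR/PYL receptors, which bind ABA, had 0 of 6 members called and 4 lower adjusted over the list alone, with a median of -1.29 (adjusted p = 0.00273, adjusted p = 0.135 with an estimated correlation). Chloroplast genes had a median of 0.51 (adjusted p = 8.84e-05, adjusted p = 0.311 with an estimated correlation). Protein-coding genes of the small RNA pathway, such as DCL and AGO genes, had a median of 0.78 (adjusted p = 0.0491, adjusted p = 0.311 with an estimated correlation, and adjusted p = 0.0841 with library-size scaling). Library-size scaling gave 22 higher and 1 lower, shifted the median gene to 0.13, and ended the calls of SEN1, AT2G33830 and BGAL4. A fit of the groups in the contrast alone gave 113 higher and 152 lower, and a replicate block 26 and 21. Without Col-0 NT total RNA replicate 1 there were 4 calls, and without Col-0 ABA total RNA replicate 2 there were 14.

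In dxo1 the same treatment was compared in total RNA. AT3G02480 was at least 27.1-fold and CRU1 at least 21.2-fold higher with ABA. RD29B gave a ratio of 39.9 with a counting interval of 6.81 to 1607 (47 counts against 1). RAB18 rose by 2.66 ± 0.55 on the log2 scale (adjusted p = 0.0384). SEN1 fell by 2.93 ± 0.44 (adjusted p = 0.00788) and AT2G33830 by 2.92 ± 0.40 (adjusted p = 0.00257). RD29A stood at 1.11 ± 0.40 and did not pass (adjusted p = 0.317). In all, 27 genes were higher and 9 lower, of which 14 and 3 were called in the same direction in Col-0, where 0.0979 and 0.00725 were expected by chance. The ABA-induced list had 2 of 13 members higher, 6 adjusted over the list alone, with a median of 0.93 (adjusted p = 6.85e-07, adjusted p = 0.04 with an estimated correlation). The seed storage list had 2 of 4 higher, 4 adjusted over the list alone, with a median of 5.30, or 3.38 with members at their bound (adjusted p = 4.05e-10, adjusted p = 0.04 with an estimated correlation). Of 91 chloroplast genes 9 were higher, 25 higher and 1 lower adjusted over the list alone, with a median of 0.74 (adjusted p = 4.04e-14, adjusted p = 0.0596 with an estimated correlation). PYR/PYL receptors had a median of -1.27 with 4 of 6 lower adjusted over the list alone (adjusted p = 3.03e-05, adjusted p = 0.0538 with an estimated correlation). Salicylate and defence genes had a median of -0.60 over 3 members (adjusted p = 0.0454, adjusted p = 0.219 with an estimated correlation). A fit of the groups in this contrast alone left 1 call and ended those of all 6 genes named as changed here. Library-size scaling gave 27 higher and 2 lower. The count was 4 without dxo1 NT total RNA replicate 1, 214 without dxo1 ABA total RNA replicate 1 and 146 without dxo1 ABA total RNA replicate 2.

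The dxo1 genotype was next compared with Col-0 in total RNA without hormone. AT1G53542 fell by 4.47 ± 0.67 and AT1G15002 by 2.7 ± 0.44 on the log2 scale in dxo1 (adjusted p = 0.0447 for both), and AT1G53542 overlaps an annotated small RNA gene. PR1, a salicylate-induced defence gene, gave a ratio of 26.6 with a counting interval of 4.49 to 1076 (38 counts against 1) and did not pass (adjusted p = 0.125). RBCS1A, the Rubisco small subunit, stood at 0.08 ± 0.44 (adjusted p = 0.952). Of 4965 genes, 0 were higher and 3 lower with edgeR, 670 had an unadjusted p under 0.05, and the DESeq2 Wald test called 34. Differences between replicates 1 and 2 correlated across genes at r = 0.235 between Col-0 NT and dxo1 NT, genes not being independent replicates, and with a replicate block 82 genes passed, 32 higher and 50 lower. The third gene was one of the 91 chloroplast genes, which had a median of -0.53 with 24 lower adjusted over the list alone (adjusted p = 2.28e-09, adjusted p = 0.236 with an estimated correlation). Mitochondrial genes had a median of -0.58 with 5 of 22 lower adjusted over the list alone (adjusted p = 0.000328, adjusted p = 0.236 with an estimated correlation). Light-harvesting and RBCS genes had a median of -0.40 (adjusted p = 0.00739, adjusted p = 0.641 with an estimated correlation, adjusted p = 0.0707 with library-size scaling), and nuclear photosystem genes -0.36 (adjusted p = 0.0241, adjusted p = 0.803 with an estimated correlation, adjusted p = 0.103 with library-size scaling). Genes of the small RNA pathway had a median of 0.65 (adjusted p = 0.0135, adjusted p = 0.238 with an estimated correlation). Salicylate genes had 0.87 (adjusted p = 0.0241, adjusted p = 0.238 with an estimated correlation). DESeq2 size factors ended both named calls, as did a fit without organelle genes, one of genes with a mean of at least 10 CPM and one of the groups in the contrast alone (0 calls each), and library-size scaling gave 2 higher and 6 lower. The count was 0 without Col-0 NT total RNA replicate 2 or dxo1 NT total RNA replicate 1, and 65 without dxo1 NT total RNA replicate 2.

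With ABA, 2 genes differed between the genotypes in total RNA. ICL, the isocitrate lyase of the glyoxylate cycle, fell by 2.54 ± 0.37 in dxo1 and the cell-wall xylosidase BXL1 by 2.36 ± 0.35 on the log2 scale (adjusted p = 0.0277 for both). RAB18 stood at -2.00 ± 0.40 and did not pass (adjusted p = 0.159). The seed storage list had a median of -1.87 with 4 of 4 members lower adjusted over the list alone (adjusted p = 7.24e-07, adjusted p = 0.082 with an estimated correlation). The ABA-induced list had a median of -0.45 with 2 of 13 lower adjusted over the list alone (adjusted p = 0.0274, adjusted p = 0.284 with an estimated correlation). Photosystem genes had a median of -0.35 (adjusted p = 0.00422, adjusted p = 0.575 with an estimated correlation) and light-harvesting and RBCS genes -0.20 (adjusted p = 0.00948, adjusted p = 0.575 with an estimated correlation). Chloroplast genes had a median of -0.30 (adjusted p = 0.000104, adjusted p = 0.35 with an estimated correlation) and mitochondrial genes -0.41 (adjusted p = 0.000762, adjusted p = 0.278 with an estimated correlation). Of 4965 genes, 488 had an unadjusted p under 0.05 and the DESeq2 Wald test called 4. With a replicate block 22 genes passed. Library-size scaling moved the median gene to -0.12 and left 0 calls. Leaving out Col-0 ABA total RNA replicate 1 or 2 also left 0, and leaving out dxo1 ABA total RNA replicate 1 gave 360.

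Whether the ABA response of total RNA differed between the genotypes was tested as an interaction. No gene passed in edgeR among 4965, where 293 had an unadjusted p under 0.05, and the DESeq2 Wald test also called 0. AE7, a factor of iron-sulfur cluster assembly, had the smallest p with an interaction of 3.58 ± 0.78 and did not pass (adjusted p = 0.697). The seed storage list had a median of -2.03, or -1.37 with members at their bound (adjusted p = 1.04e-05, adjusted p = 0.115 with an estimated correlation). Genes of the small RNA pathway had a median of -1.12 (adjusted p = 0.00383, adjusted p = 0.287 with an estimated correlation). Adjusted over the list alone, 1 of 6 was lower. Chloroplast genes had a median of 0.30 (adjusted p = 0.0113, adjusted p = 0.429 with an estimated correlation). Library-size scaling moved the median gene to -0.22, and without dxo1 NT total RNA replicate 2 there were 10 calls. The interaction was not simulated for total RNA. In data simulated for ABA in Col-0, the fit recovered 3.23% of changes of log2 1, 58.1% of log2 2 and 80% of log2 3.

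NAD libraries were then set against total RNA of the same condition, to ask which transcripts were over-represented after capture. No mock capture was analysed here, so a higher level in NAD libraries is not by itself a measure of NAD caps. In Col-0 NT, the photosystem II genes named here were higher in NAD libraries, with log2 fold changes of 2.74 ± 0.40 for PSBX (adjusted p = 6.12e-05), 2.49 ± 0.46 for PSBY (adjusted p = 0.00128) and 1.95 ± 0.43 for PSBQ1 (adjusted p = 0.00757). The antenna genes LHCB1.4, LHCB1.2 and LHCB1.1 stood at 1.4 ± 0.34, 1.39 ± 0.39 and 1.36 ± 0.39, with the largest adjusted p at 0.0451. CHLP, which makes the phytyl tail of chlorophyll, was higher by 1.34 ± 0.33 (adjusted p = 0.019), the tubulin TUB2 by 2.17 ± 0.48 (adjusted p = 0.00774) and the auxin-conjugating enzyme GH3.3 by 3.20 ± 0.87 (adjusted p = 0.0326). The mitochondrial ATMG01390 was higher by 3.92 ± 1.02 (adjusted p = 0.0251). RBCS1A stood at 0.11 ± 0.38 (adjusted p = 0.933) and LHCB2.3 at 0.79 ± 0.35 (adjusted p = 0.23).

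Lower in NAD libraries of Col-0 NT were the snoRNA AT1G74453 (-7.40 ± 0.80), the chloroplast ATCG00230 (-6.78 ± 1.04) and the mitochondrial ATMG00070 (-2.38 ± 0.36), with adjusted p of 1.67e-06, 0.000141 and 8.92e-05. Among protein-coding genes, AT1G72645 was lower by -8.04 ± 0.84, AT4G15030 by -7.66 ± 0.75 and PRIN2, a factor of plastid transcription, by -2.50 ± 0.50, with adjusted p of 1.47e-06, 1.37e-06 and 0.00259. AT1G72645 overlaps an annotated small RNA gene and AT4G15030 overlaps none. Of 5475 genes tested, 83 were higher and 151 lower, and of 51 snoRNA genes 16 were lower with a class median of -1.73. Photosystem genes had 5 of 25 members higher and 0 lower, 11 adjusted over the list alone, with a median of 0.72 (adjusted p = 3.29e-06, adjusted p = 0.797 with an estimated correlation). Light-harvesting and RBCS genes had 3 of 21 higher, 4 adjusted over the list alone, with a median of 0.71 (adjusted p = 0.00106, adjusted p = 0.797 with an estimated correlation). Library-size scaling moved the median gene to -0.26, left 2 higher and 74 lower, and ended the calls of every higher nuclear gene named here, and of PRIN2 and ATMG00070. Without NAD replicate 1, NAD replicate 2, total RNA replicate 1 or total RNA replicate 2 of Col-0 NT the counts were 91, 116, 104 and 115, and ATMG01390 lost its call in each case.

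In Col-0 with ABA, 64 genes were higher and 96 lower in NAD libraries, of which replicate 1 stood apart with protein-coding genes at 2.17% of its counts against 11.2% in replicate 2. CRU1 was lower by -2.23 ± 0.54 (adjusted p = 0.0291) and the mitochondrial ATMG00070 by -2.44 ± 0.36 (adjusted p = 0.000314). PYR1, an ABA receptor, was higher by 1.98 ± 0.53 (adjusted p = 0.0393), the chloroplast ATCG00950 by 5.49 ± 0.68 (adjusted p = 3.95e-05), and AT3G05155 was at least 20.5-fold higher. Photosystem genes had 0 of 25 members called and 1 higher adjusted over the list alone, and their median of 0.53 turned to -0.40 with library-size scaling (adjusted p = 0.00615, adjusted p = 0.636 with an estimated correlation, adjusted p = 0.818 with library-size scaling). Of 51 snoRNA genes 10 were lower, with a median of -1.64. Library-size scaling moved the median gene to -1.34 and gave 5 higher and 378 lower. Without NAD replicate 1, NAD replicate 2, total RNA replicate 1 or total RNA replicate 2 of this condition the counts were 95, 64, 46 and 43.

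In dxo1 NT the same comparison called 385 genes higher and 353 lower. The ribosomal protein gene AT3G08520 gave a ratio of 141 with a counting interval of 38.5 to 1171 (207 counts against 2). KIN2, a cold- and ABA-induced gene, was higher by 2.43 ± 0.46 (adjusted p = 0.000974), PSBX by 2.28 ± 0.37 (adjusted p = 0.000255), LHCB1.2 by 1.91 ± 0.39 (adjusted p = 0.00218), RAB18 by 2.44 ± 0.78 (adjusted p = 0.037) and the chloroplast regulator GLK2 by 1.81 ± 0.58 (adjusted p = 0.0372). Lower were the decapping activator LSM1A at -2.43 ± 0.65 (adjusted p = 0.0136), DCL2 of the small RNA pathway at -2.67 ± 0.78 (adjusted p = 0.0243), the cytokinesis gene KNOLLE at -2.98 ± 0.88 (adjusted p = 0.0262), HEMA1 of tetrapyrrole synthesis at -1.10 ± 0.33 (adjusted p = 0.0281) and LOX2 of jasmonate synthesis at -1.30 ± 0.43 (adjusted p = 0.045). Library-size scaling ended the calls of these genes other than AT3G08520. Photosystem genes had 14 of 25 members higher and 1 lower, 17 and 1 adjusted over the list alone, with a median of 1.15 (adjusted p = 4.76e-07, adjusted p = 0.449 with an estimated correlation). Light-harvesting and RBCS genes had 7 of 21 higher, 9 adjusted over the list alone, with a median of 0.56 (adjusted p = 0.000579, adjusted p = 0.643 with an estimated correlation). ABA-induced genes had 2 of 18 higher with a median of 0.98, or 0.88 with members at their bound (adjusted p = 0.00672, adjusted p = 0.449 with an estimated correlation). Chloroplast genes had 30 of 96 higher and 4 lower with a median of 0.68 (adjusted p = 4.76e-07, adjusted p = 0.334 with an estimated correlation) and mitochondrial genes 8 of 25 higher with a median of 0.44 (adjusted p = 0.00554, adjusted p = 0.334 with an estimated correlation). Of 51 snoRNA genes 10 were higher and 14 lower, with a median of 0.83, beside a snoRNA share of 3.87% ± 3.85 in dxo1 NT total RNA. Library-size scaling gave 50 higher and 48 lower. Without NAD replicate 1, NAD replicate 2, total RNA replicate 1 or total RNA replicate 2 of dxo1 NT the counts were 263, 277, 348 and 338.

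In dxo1 with ABA, 294 genes were higher and 330 lower in NAD libraries. AT3G05155 was at least 49.5-fold higher and SOFL2, which overlaps an annotated small RNA gene, at least 33.2-fold. COR15A, a cold- and ABA-induced chloroplast protein, gave a ratio of 28.7 with a counting interval of 7.35 to 246 (34 counts against 2). KIN2 was higher by 2.11 ± 0.42 (adjusted p = 0.00233), the photosystem I gene PSAN by 1.68 ± 0.35 (adjusted p = 0.00309) and LHCB1.1 by 1.59 ± 0.39 (adjusted p = 0.00965). The ABA synthesis gene ABA1 was lower by -1.19 ± 0.35 (adjusted p = 0.0277), and the snoRNAs AT1G20015 and AT4G39366 by -7.49 ± 1.04 and -7.48 ± 1.00, with adjusted p of 0.000133 and 8.82e-05. Photosystem genes had 13 of 25 members higher and 1 lower, 15 and 1 adjusted over the list alone, with a median of 1.19 (adjusted p = 4e-08, adjusted p = 0.553 with an estimated correlation). Light-harvesting and RBCS genes had 4 of 21 higher, 8 adjusted over the list alone, with a median of 0.66 (adjusted p = 0.000306, adjusted p = 0.553 with an estimated correlation). ABA-induced genes had 2 of 18 higher with a median of 0.80 (adjusted p = 0.00531, adjusted p = 0.553 with an estimated correlation). Of 51 snoRNA genes 19 were lower with a median of -1.75, beside a snoRNA share of 45.2% ± 15.4 in dxo1 ABA total RNA. Scaling by library size put the median gene at 0.21, gave 13 higher and 27 lower, and ended the calls of KIN2, PSAN, LHCB1.1, ABA1 and COR15A. Without NAD replicate 1, NAD replicate 2, total RNA replicate 1 or total RNA replicate 2 of dxo1 ABA the counts were 121, 114, 1042 and 178.

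**Figure D2:**
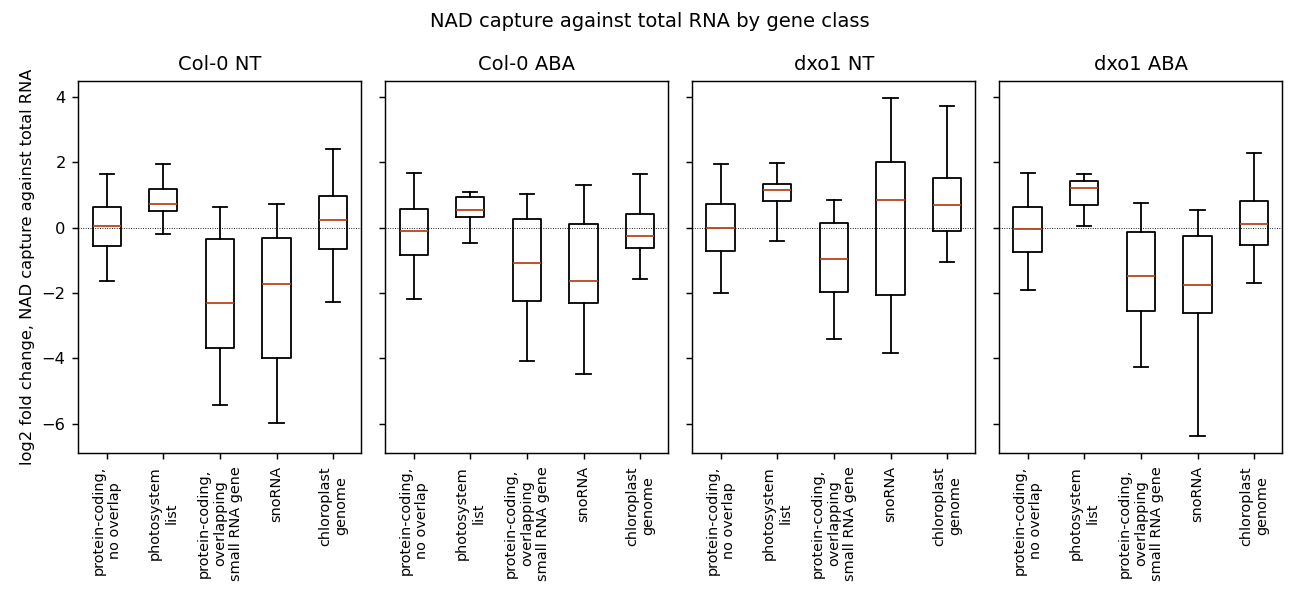
Log2 fold change of NAD over total RNA by class of gene in the 4 conditions, with boxes from the 25th to the 75th percentile, a line at the median and whiskers at the 5th and 95th percentiles. Nuclear photosystem genes had medians of 0.72, 0.53, 1.15 and 1.19 in Col-0 NT, Col-0 ABA, dxo1 NT and dxo1 ABA, of which that of Col-0 ABA turned to -0.40 with library-size scaling.

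Across the 4 conditions, 16 genes were higher in NAD libraries every time, 10 of them protein-coding and 6 chloroplast-encoded. They included CP12-1, a regulator of the Calvin cycle, with log2 fold changes of 1.98 ± 0.34, 2.96 ± 0.36, 3.58 ± 0.35 and 3.24 ± 0.35 in Col-0 NT, Col-0 ABA, dxo1 NT and dxo1 ABA. The metallothioneins MT2B (1.57 ± 0.36 to 2.55 ± 0.36) and MT3 (1.06 ± 0.34 to 1.66 ± 0.35) were also among them. Lower in all 4 conditions were 42 genes, 25 of them protein-coding, 9 snoRNA genes and 4 other non-coding genes. In Col-0 NT these included the translation factor EIF4A1 at -3.15 ± 0.64, the ferredoxin FD3 at -5.68 ± 0.68, the small GTPase ARF1A1C at -2.50 ± 0.45 and the spliceosomal RNA U2.7 at -5.06 ± 0.73. These genes were chosen after their values were seen. Of the 25 protein-coding genes, 15 overlap an annotated small RNA gene on either strand, among them EIF4A1 and ARF1A1C, against 21 of 4752 protein-coding genes never called lower (15 and 10 on the same strand). With library-size scaling MT2B and MT3 lost their calls in all 4 conditions, and CP12-1 lost those in Col-0.

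The change of NAD enrichment, that is of the ratio of NAD to total RNA, was tested between conditions. For ABA in Col-0, AT4G23420 had the smallest p with 3.36 ± 0.64 and did not pass (adjusted p = 0.104), and RD29A stood at -1.65 ± 0.65 (adjusted p = 0.529). No gene of 5475 passed in edgeR, 468 had an unadjusted p under 0.05, and the DESeq2 Wald test called 11. With library-size scaling the median gene moved to -1.05. Without Col-0 ABA NAD replicate 2, 10 genes passed.

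For ABA in dxo1, 2 genes had lower NAD enrichment. One was the spliceosomal RNA U6-29, with 58 counts in dxo1 NT NAD libraries, 66 in dxo1 ABA NAD libraries, 1 in dxo1 NT total RNA and 262 in dxo1 ABA total RNA (adjusted p = 0.000343). The other was a chloroplast gene without a name in the reference table. Chloroplast genes had a median of -0.71 with 1 higher and 16 lower of 96 adjusted over the list alone (adjusted p = 1.38e-09, adjusted p = 0.316 with an estimated correlation). The edgeR count of 2 stood beside 208 genes with an unadjusted p under 0.05 and 2 calls by the DESeq2 Wald test. Scaling by library size alone shifted the median gene to 0.13. The count was 25 without dxo1 NT total RNA replicate 2, 6 without dxo1 ABA total RNA replicate 1 and 11 without dxo1 ABA total RNA replicate 2, and 1 without any other of the 8 libraries.

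For dxo1 against Col-0 in NT, NAD enrichment of AT1G15002 rose by 3.55 ± 0.62 on the log2 scale (adjusted p = 0.0296). Its total RNA level was 71.3 ± 9.05 CPM in Col-0 and 11.2 ± 0.874 in dxo1, and its NAD level 17.3 ± 4.69 and 43.2 ± 5.07 (SD, n = 2). RBCS1A stood at -0.53 ± 0.54 (adjusted p = 0.827). Mitochondrial genes had 8 of 25 members higher adjusted over the list alone and 0 over all genes, with a median of 1.13 (adjusted p = 5.02e-07, adjusted p = 0.0435 with an estimated correlation). Chloroplast genes had 15 of 96 higher adjusted over the list alone and 0 over all genes, with a median of 0.58 (adjusted p = 2.15e-06, adjusted p = 0.406 with an estimated correlation). With edgeR 1 of 5475 genes passed, 506 had an unadjusted p under 0.05, and the DESeq2 Wald test called 39. The median gene moved to 0.36 with library-size scaling, and this scaling ended the call of AT1G15002, which was also lost without any of 5 single libraries. The count was 10 without Col-0 NT NAD replicate 2, 5 without Col-0 NT total RNA replicate 1, 78 without dxo1 NT total RNA replicate 2 and 0 without any 1 of the 5 others.

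With ABA, NAD enrichment was also compared between the genotypes. In edgeR 0 of 5475 genes passed, 299 had an unadjusted p under 0.05, and the DESeq2 Wald test called 0. AT3G07480 (3.48 ± 0.89) and the stress-associated SAP5 (2.78 ± 0.75) had the smallest p and did not pass (adjusted p = 0.822 for both). ABA-induced genes had a median of 1.01 with 0 of 18 called (adjusted p = 0.00859, adjusted p = 0.672 with an estimated correlation). With library-size scaling the median gene moved to 1.57, and without dxo1 ABA total RNA replicate 1 there were 8 calls.

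The interaction of genotype and ABA on NAD enrichment gave 0 calls among 5475 genes in edgeR, with 276 at an unadjusted p under 0.05 and 0 by the DESeq2 Wald test. AT3G56020 had the smallest p with -4.87 ± 1.21 and did not pass (adjusted p = 0.901). Chloroplast genes had a median of -0.29, which turned to 0.75 with library-size scaling (adjusted p = 0.00764, adjusted p = 0.649 with an estimated correlation). Mitochondrial genes had a median of -0.77, which turned to 0.35 with library-size scaling (adjusted p = 0.00722, adjusted p = 0.432 with an estimated correlation). That scaling moved the median gene to 1.19, and without dxo1 NT total RNA replicate 2 there were 32 calls. Simulated changes of NAD enrichment by ABA in Col-0 were recovered at 0% for log2 1, 15.4% for log2 2 and 48.4% for log2 3.

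GMUCT over total RNA was used as a measure of uncapped transcript relative to abundance. For ABA in Col-0 the ratio rose for AT1G64490 by 4.55 ± 0.58 (adjusted p = 7.89e-06), the haemoglobin HB1 by 4.35 ± 0.85 (adjusted p = 0.00605) and the dehydrin ERD14 by 2.44 ± 0.40 (adjusted p = 0.000776). It fell for RBCS1B by 2.55 ± 0.65 on the log2 scale (adjusted p = 0.0473) and for the microRNA-processing enzyme DCL1 by 2.54 ± 0.62 (adjusted p = 0.0385). RD29A stood at 1.32 ± 0.49 (adjusted p = 0.237). Of 17930 genes 45 were higher and 67 lower. Chloroplast genes had 8 of 99 lower, 26 lower and 1 higher adjusted over the list alone, with a median of -0.85 (adjusted p = 0.00213, adjusted p = 0.601 with an estimated correlation). The seed storage list had a fitted median of -1.13 and mean of -0.97, while its median was 5.81 with members at their bound and 0.95 with library-size scaling and camera ranked it upward (adjusted p = 0.01, adjusted p = 0.311 with an estimated correlation), so its direction was not settled. Library-size scaling moved the median gene to -0.26 from -0.13, gave 8 higher and 21 lower, and ended the calls of ERD14, DCL1 and RBCS1B, while DESeq2 size factors gave 52 higher and 42 lower. The count was 7 without total RNA replicate 1 of Col-0 NT or of Col-0 ABA, 20 without Col-0 ABA total RNA replicate 2 or Col-0 ABA GMUCT replicate 1, and 32 and 42 without Col-0 NT GMUCT replicate 1 and 2.

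For ABA in dxo1, the ratio rose for the clock gene PRR5 by 2.87 ± 0.60 (adjusted p = 0.0237) and fell for AT1G74456 by 4.99 ± 0.79 on the log2 scale (adjusted p = 0.00208). Chloroplast genes had 6 of 99 lower, 26 lower and 1 higher adjusted over the list alone, with a median of -1.01 (adjusted p = 1.57e-10, adjusted p = 0.475 with an estimated correlation). In all 8 genes were higher and 17 lower. Library-size scaling gave 3 higher and 13 lower and ended the call of PRR5, and DESeq2 size factors gave 7 higher and 7 lower. A fit of the groups in this contrast alone gave 0 calls, where the DESeq2 Wald test gave 99. The count was 3 without dxo1 NT GMUCT replicate 1, 15 without dxo1 NT GMUCT replicate 2, 7 and 8 without dxo1 ABA GMUCT replicate 1 and 2, 6 and 56 without dxo1 NT total RNA replicate 1 and 2, and 168 and 119 without dxo1 ABA total RNA replicate 1 and 2.

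For dxo1 against Col-0 in NT, the ratio rose for AE7 by 3.43 ± 0.74 (adjusted p = 0.025) and the non-coding AT5G01175 by 2.81 ± 0.46 (adjusted p = 0.00409), and fell for AT1G14460 by 3.42 ± 0.60 on the log2 scale (adjusted p = 0.00409). The level of AE7 in total RNA was 16.7 ± 4.25 CPM in Col-0 and 1.55 ± 0.523 in dxo1, against 7.73 ± 2.86 and 8.95 ± 2.92 in GMUCT (SD, n = 2). Of 17930 genes 11 were higher and 23 lower, while library-size scaling gave 11 higher and 2 lower with a median gene at 0.16 and DESeq2 size factors gave 10 and 13. Photosystem genes had a median of -0.54 with 0 of 25 called (adjusted p = 0.0383, adjusted p = 0.788 with an estimated correlation, adjusted p = 0.342 with library-size scaling). The count was 0 and 3 without Col-0 NT GMUCT replicate 1 and 2, 11 without dxo1 NT GMUCT replicate 2, 7 and 19 without Col-0 NT total RNA replicate 1 and 2, and 77 without dxo1 NT total RNA replicate 2.

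With ABA, 18 genes were higher and 83 lower in dxo1 than in Col-0. The ratio rose for the pectin methylesterase ATPMEPCRB by 3.23 ± 0.57 (adjusted p = 0.00218) and the decapping scaffold VCS by 2.04 ± 0.50 (adjusted p = 0.0405), and fell for ERD14 by 1.79 ± 0.40 on the log2 scale (adjusted p = 0.0209). The flavonoid list had a median of -2.00, or -1.72 with members at their bound, with 4 of 11 lower adjusted over the list alone and 0 over all genes (adjusted p = 0.00413, adjusted p = 0.0919 with an estimated correlation). The seed storage list had a median of -1.01, or -1.09 with members at their bound, with 2 of 10 lower adjusted over the list alone (adjusted p = 0.0194, adjusted p = 0.203 with an estimated correlation). With library-size scaling the median gene stood at 0.37, and this scaling gave 12 higher and 2 lower, and ended the calls of VCS and ERD14. The count was 19 and 51 without Col-0 ABA GMUCT replicate 1 and 2, 47 without dxo1 ABA GMUCT replicate 2, 7 and 18 without Col-0 ABA total RNA replicate 1 and 2, and 541 and 61 without dxo1 ABA total RNA replicate 1 and 2.

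The interaction on GMUCT over total RNA called AT1G64490 alone, at -4.21 ± 0.75 (adjusted p = 0.022). Its total RNA level was 39.5 ± 33.2 CPM in Col-0 NT and 4.65 ± 3.66 in Col-0 ABA, so the replicates spread widely (SD, n = 2). With library-size scaling 1 gene was lower and the median gene stood at 0.23, and the DESeq2 Wald test called 47. The call of AT1G64490 was lost without any of 11 single libraries of the 16, the count was 2 without dxo1 NT GMUCT replicate 1, and 31, 18 and 59 genes passed without dxo1 NT total RNA replicate 2, dxo1 ABA total RNA replicate 1 and dxo1 ABA total RNA replicate 2. Simulated changes of the ratio by ABA in Col-0 were recovered at 0% for log2 1, 25.4% for log2 2 and 60.6% for log2 3.

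Because the GMUCT libraries held far more counts in genes, their own levels were also compared, a choice made after the depths were seen. Such levels reflect transcript abundance as well as decapping and cleavage. With ABA, seed and desiccation transcripts rose in GMUCT libraries of Col-0. RAB18 went from 19.5 ± 1.35 to 2056 ± 138 CPM and RD29B from 3.5 ± 0.388 to 1344 ± 75.3 (SD, n = 2), with log2 fold changes of 6.85 ± 0.22 and 8.72 ± 0.25. EM1, a LEA protein, rose by 9.52 ± 0.31, RD29A by 2.84 ± 0.17 and COR15A by 3.52 ± 0.19. AT5G55410 was at least 951-fold higher, and AT3G15670 gave a ratio of 5375 with a counting interval of 1487 to 44394. CRU1 rose by 9.10 ± 0.26, CRU3 by 9.54 ± 0.27 and OLEO2 by 11.55 ± 0.32. The ABA-degrading enzymes CYP707A1 and CYP707A3 rose by 3.55 ± 0.21 and 2.06 ± 0.19, and the phosphatases HAI1, HAI2 and AHG1, which restrain ABA signalling, by 3.27 ± 0.44, 5.04 ± 0.27 and 4.76 ± 0.51. Lower were AT1G05700 (-5.18 ± 0.31), AT1G66100 (-4.51 ± 0.23), AT3G16670 (-4.40 ± 0.22), the peroxidase PRXCA (-4.04 ± 0.28) and the lipid transfer proteins EARLI1 (-4.00 ± 0.21) and AZI1 (-2.23 ± 0.16). The largest adjusted p among these genes was 1.35e-05. The exonuclease XRN4 fell by 0.93 ± 0.18 on the log2 scale (adjusted p = 0.000606), NUDT7 rose by 1.23 ± 0.18 (adjusted p = 2.84e-05), and DXO1 stood at 0.17 ± 0.18 (adjusted p = 0.518).

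In this comparison 2745 of 19644 genes were higher and 2505 lower. ABA-induced genes had 24 of 32 members higher and 4 lower, 25 and 4 adjusted over the list alone, with a median of 1.37 (adjusted p = 4.24e-12, adjusted p = 0.0488 with an estimated correlation). Clade A phosphatases had 7 of 9 higher, the same number adjusted over the list alone, with a median of 0.99 (adjusted p = 0.000252, adjusted p = 0.0945 with an estimated correlation). Flavonoid genes had 10 of 11 higher, 11 adjusted over the list alone, with a median of 2.59 (adjusted p = 1.15e-10, adjusted p = 0.0212 with an estimated correlation). Among them DFR rose by 5.04 ± 0.31, CHS by 2.59 ± 0.17 and UGT75C1 by 3.35 ± 0.23. All 10 seed storage genes tested were higher, with a median of 9.32, or 7.25 with members at their bound (adjusted p = 9.3e-16, adjusted p = 0.0212 with an estimated correlation). Jasmonate genes had 7 of 18 higher, 8 adjusted over the list alone, with a median of 0.54 (adjusted p = 0.00261, adjusted p = 0.0945 with an estimated correlation), led by VSP2 at 2.12 ± 0.21 and AOC2 at 1.43 ± 0.18. Plastid transcription genes had 9 of 16 lower, 10 adjusted over the list alone, with a median of -0.57 (adjusted p = 0.000526, adjusted p = 0.0742 with an estimated correlation), among them SIG4 at -1.11 ± 0.18 and PTAC12 at -1.08 ± 0.18. Salicylate and defence genes had 4 of 26 higher and 12 lower with a median of -0.64, or -0.53 with members at their bound (adjusted p = 0.0303, adjusted p = 0.179 with an estimated correlation, adjusted p = 0.0887 with library-size scaling). In that list PR5 was at least 11.4-fold lower and WRKY18 rose by 1.88 ± 0.16.

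The other lists did not pass the camera test for ABA in Col-0 GMUCT libraries. PYR/PYL receptors had 1 of 10 higher, which was PYL4 at 0.52 ± 0.16 (adjusted p = 0.0239) and was lost without any 1 library and with library-size scaling. ABA synthesis and catabolism had 2 of 8 higher and 1 lower, light harvesting and RBCS 5 of 21 higher, nuclear photosystem subunits 2 of 25 higher and 1 lower, and chlorophyll synthesis 3 of 18 higher and 1 lower. mRNA decay had 2 of 25 higher and 3 lower, the small RNA pathway 2 of 17 lower, heat shock 1 of 9 higher, and the cell cycle 2 of 24 lower. Root genes had 6 of 20 higher and 6 lower, the single tested floral gene was lower, and of 9 reference genes 1 was higher. Chloroplast genes had 6 of 82 higher and 17 lower, and mitochondrial genes 2 of 27 higher and 3 lower. Scaling by library size alone shifted the median gene to -0.14, and this scaling gave 2121 higher and 3671 lower. The count of 5250 became 2963 and 3132 without Col-0 NT GMUCT replicate 1 and 2.

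In dxo1 GMUCT libraries ABA raised the same kinds of transcripts. RAB18 went from 13.1 ± 2.76 to 283 ± 20.6 CPM and RD29B from 3.22 ± 0.525 to 303 ± 50.7 (SD, n = 2), with log2 fold changes of 4.45 ± 0.20 and 6.57 ± 0.23. RD29A rose by 1.89 ± 0.17, COR15A by 3.05 ± 0.17, HAI1 by 3.33 ± 0.41, HAI2 by 3.79 ± 0.30, CRU3 by 7.96 ± 0.27 and the jasmonate enzyme LOX4 by 2.63 ± 0.17. PER1, a seed peroxiredoxin, was at least 514-fold higher and AT2G15010 at least 180-fold. PR1 fell by 3.44 ± 0.27 on the log2 scale, AACT1 by 5.12 ± 0.38, CYP71B22 by 3.92 ± 0.27 and the receptor gene PYL6 by 2.23 ± 0.21. The largest adjusted p among these was 1.24e-05. In all, 1012 of 19644 genes were higher and 497 lower, of which 609 and 340 were also called in that direction in Col-0, where 141 and 63.4 were expected by chance.

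By list, ABA-induced genes had 24 of 32 higher, 25 adjusted over the list alone, with a median of 1.05 (adjusted p = 4.92e-26, adjusted p = 0.0167 with an estimated correlation). Clade A phosphatases had 6 of 9 higher with a median of 1.07 (adjusted p = 8.95e-08, adjusted p = 0.0463 with an estimated correlation). Flavonoid genes had 6 of 11 higher, 10 adjusted over the list alone, with a median of 0.85 (adjusted p = 9.12e-08, adjusted p = 0.0274 with an estimated correlation). Seed storage genes had 8 of 10 higher with a median of 7.77, or 7.37 with members at their bound (adjusted p = 8.46e-21, adjusted p = 0.0166 with an estimated correlation). ABA synthesis and catabolism genes had 2 of 8 higher with a median of 0.47 (adjusted p = 0.000366, adjusted p = 0.136 with an estimated correlation). PYR/PYL receptors had 1 of 10 higher and 2 lower (median -0.35, adjusted p = 0.0175, adjusted p = 0.192 with an estimated correlation). Root genes had 3 of 20 higher (median 0.20, adjusted p = 0.00301, adjusted p = 0.213 with an estimated correlation). Jasmonate genes had 5 of 18 higher and 2 lower (median 0.09, adjusted p = 0.0328, adjusted p = 0.192 with an estimated correlation), and genes of the small RNA pathway 1 of 17 lower (median -0.11, adjusted p = 0.0424, adjusted p = 0.313 with an estimated correlation). Salicylate genes had 5 of 26 higher and 8 lower and did not pass the list test (adjusted p = 0.163).

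Without hormone, dxo1 was compared with Col-0 in GMUCT libraries. PR1 went from 1.27 ± 0.952 to 40.6 ± 6.35 CPM (SD, n = 2), a log2 fold change of 4.91 ± 0.32. PR2, a secreted glucanase, rose by 2.45 ± 0.26, PAD3 of camalexin synthesis by 2.96 ± 0.38, LURP1 by 3.51 ± 0.29 and AT5G60250 by 3.99 ± 0.38. The anthocyanin genes DFR, UGT75C1 and CHS rose by 3.34 ± 0.33, 1.65 ± 0.23 and 1.08 ± 0.16. LHCB6 fell from 1035 ± 30.0 to 445 ± 70.2 CPM, and PSBW, PSAD1 and the plastocyanin PETE2 fell by 1.42 ± 0.17, 1.24 ± 0.15 and 1.33 ± 0.17 on the log2 scale. The dormancy-associated DYL1 went from 1593 ± 6.94 to 211 ± 20.7 CPM. AT2G05510 fell by 2.90 ± 0.21 and the phloem lectin PP2-A1 by 2.78 ± 0.25. Among ABA genes, the transcription factor RD26 fell by 1.79 ± 0.16, the dehydrin LTI30 by 1.36 ± 0.16, the phosphatase PP2CA by 1.00 ± 0.16, the receptor PYL5 by 1.18 ± 0.15 and NCED3, the rate-limiting step of ABA synthesis, by 1.32 ± 0.27. The hydrolases NUDT19 and NUDT7 rose by 0.98 ± 0.19 and 0.87 ± 0.17, the nuclear exonuclease XRN2 by 0.70 ± 0.17 and the RNA silencing genes AGO2, DCL2 and DCL1 by 0.93 ± 0.18, 0.91 ± 0.18 and 0.60 ± 0.16. GUN4 of chlorophyll synthesis rose by 0.96 ± 0.17. The largest adjusted p among these genes was 0.0108, RBCS1A stood at -0.08 ± 0.16 (adjusted p = 0.763) and LHCB2.3 at 0.19 ± 0.17 (adjusted p = 0.482).

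Of 19644 genes, 1981 were higher and 2037 lower. Salicylate and defence genes had 15 of 26 higher and 1 lower, 17 and 1 adjusted over the list alone, with a median of 1.15 (adjusted p = 2.52e-07, adjusted p = 0.106 with an estimated correlation). Photosystem genes had 17 of 25 lower, 22 adjusted over the list alone, with a median of -0.78 (adjusted p = 1.85e-11, adjusted p = 0.319 with an estimated correlation). Light-harvesting and RBCS genes had 9 of 21 lower, 11 adjusted over the list alone, with a median of -0.45 (adjusted p = 0.000117, adjusted p = 0.383 with an estimated correlation). Chloroplast genes had 3 of 82 higher and 32 lower (median -0.65, adjusted p = 2.4e-09, adjusted p = 0.319 with an estimated correlation) and mitochondrial genes 7 of 27 lower (median -0.60, adjusted p = 0.000791, adjusted p = 0.37 with an estimated correlation). Clade A phosphatases had 4 of 9 lower (median -0.65, adjusted p = 0.013, adjusted p = 0.319 with an estimated correlation). ABA-induced genes had 1 of 32 higher and 11 lower, and their median of -0.14 turned to 0.01 with library-size scaling (adjusted p = 0.0296, adjusted p = 0.319 with an estimated correlation). Flavonoid genes had 5 of 11 higher and 1 lower (median 0.93, adjusted p = 0.013, adjusted p = 0.296 with an estimated correlation), jasmonate genes 5 of 18 higher (median 0.44, adjusted p = 0.000891, adjusted p = 0.194 with an estimated correlation) and genes of the small RNA pathway 4 of 17 higher (median 0.36, adjusted p = 0.013, adjusted p = 0.319 with an estimated correlation). Of the reference genes, UBQ10 and GAPC2 fell by 0.79 ± 0.16 and 0.65 ± 0.16. The median gene moved to 0.17 with library-size scaling, and this scaling gave 3475 higher and 1301 lower. The count was 1683 and 1359 without Col-0 NT GMUCT replicate 1 and 2, and 2337 without dxo1 NT GMUCT replicate 2, while the calls of ABI2, DCL1, RAB18 and COR15A were lost in 3 or more of the 4 fits.

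With ABA, dxo1 was again compared with Col-0 in GMUCT libraries. EM1 fell by 4.17 ± 0.21 on the log2 scale, RAB18 by 3.13 ± 0.18, OLEO2 by 3.08 ± 0.18, HAI3 by 3.06 ± 0.29, RD29B by 2.42 ± 0.17 and the anthocyanin enzyme UF3GT by 2.4 ± 0.28. RD29A fell by 0.88 ± 0.16 (adjusted p = 0.000387), while COR15A stood at 0.17 ± 0.15 and did not pass (adjusted p = 0.425). CRU2 had 176 counts in Col-0 and 1 in dxo1, 316-fold lower with a counting interval of 55.9 to 12537. Higher were the defence regulators WRKY46 by 4.06 ± 0.41 and WRKY33 by 2.23 ± 0.16, LOX4 by 1.95 ± 0.18 and the plastid sigma factor SIG5 by 1.38 ± 0.24. BHLH100, a regulator of iron uptake, had 215 counts in dxo1 and 1 in Col-0, a ratio of 120 with a counting interval of 21.3 to 4757. PSBW fell by 1.64 ± 0.17, LHCA2 by 1.36 ± 0.17 and the nonsense-mediated decay factor UPF2 by 1.02 ± 0.17, and GUN4 rose by 1.16 ± 0.17.

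In all 2917 of 19644 genes were higher and 3108 lower, of which 1013 and 958 were called in the same direction without hormone, where 294 and 322 were expected by chance. Seed storage genes had 8 of 10 lower with a median of -2.80 (adjusted p = 2.63e-07, adjusted p = 0.0549 with an estimated correlation). Flavonoid genes had 10 of 11 lower (median -0.94, adjusted p = 1.74e-05, adjusted p = 0.0549 with an estimated correlation). ABA-induced genes had 2 of 32 higher and 18 lower, 4 and 20 adjusted over the list alone (median -0.57, adjusted p = 8.48e-05, adjusted p = 0.144 with an estimated correlation), and clade A phosphatases 6 of 9 lower (median -0.92, adjusted p = 0.00119, adjusted p = 0.144 with an estimated correlation). Salicylate and defence genes had 13 of 26 higher, 15 adjusted over the list alone, with a median of 1.06, or 0.98 with members at their bound (adjusted p = 2.63e-07, adjusted p = 0.0549 with an estimated correlation). Photosystem genes had 16 of 25 lower (median -0.66, adjusted p = 3.52e-07, adjusted p = 0.453 with an estimated correlation) and light-harvesting and RBCS genes 1 of 21 higher and 11 lower (median -0.55, adjusted p = 0.000722, adjusted p = 0.468 with an estimated correlation). Plastid transcription genes had 5 of 16 higher (median 0.41, adjusted p = 0.0206, adjusted p = 0.152 with an estimated correlation) and cell cycle genes 6 of 24 higher and 1 lower (median 0.48, adjusted p = 0.0146, adjusted p = 0.144 with an estimated correlation). Heat shock genes had 2 of 9 lower (median -0.62, adjusted p = 0.0484, adjusted p = 0.468 with an estimated correlation). Chloroplast genes had 7 of 82 higher and 33 lower (median -0.44, adjusted p = 0.00166, adjusted p = 0.487 with an estimated correlation) and mitochondrial genes 2 of 27 higher and 9 lower (median -0.76, adjusted p = 0.00176, adjusted p = 0.468 with an estimated correlation). With library-size scaling the median gene moved to 0.28, and this scaling gave 5642 higher and 1907 lower.

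**Figure D3:**
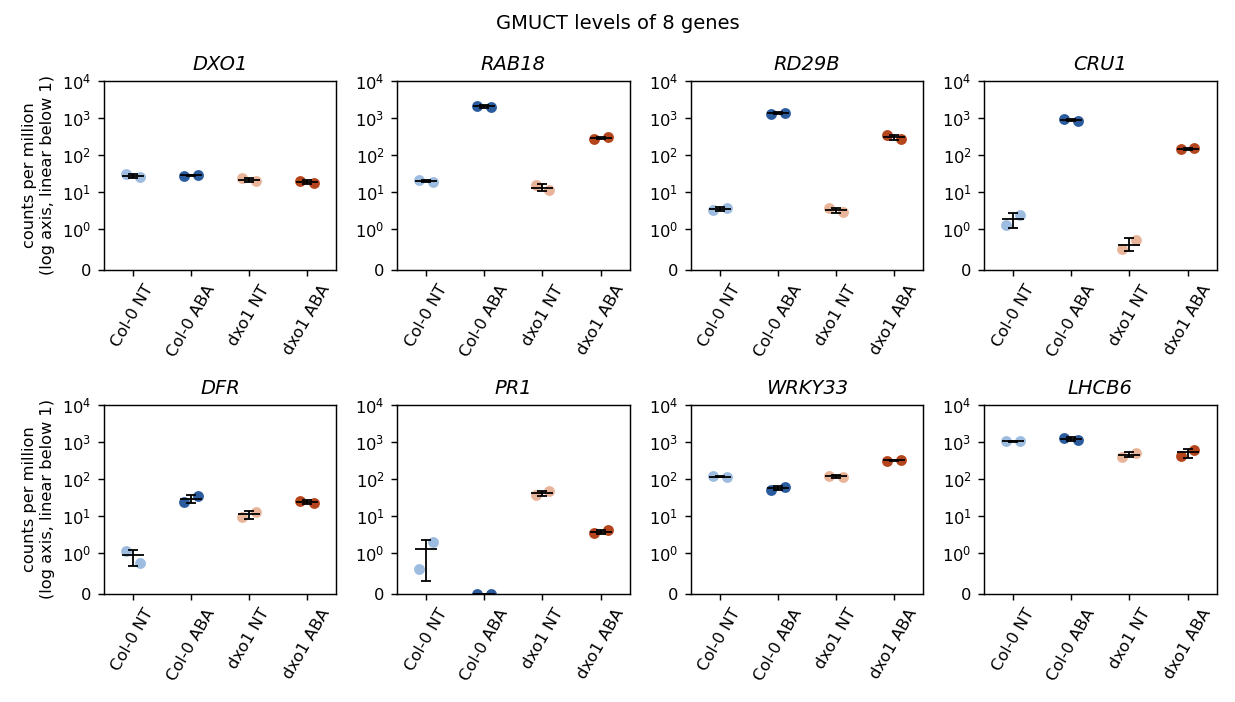
Levels of selected transcripts in GMUCT libraries in CPM, on an axis that is linear below 1 and logarithmic above, with points for libraries and bars for the mean ± SD (n = 2) of each group. RAB18 reached 2056 ± 138 in Col-0 ABA and 283 ± 20.6 in dxo1 ABA.

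Whether dxo1 responded to ABA differently from Col-0 was tested as the interaction in GMUCT libraries. The responses of RAB18, RD29B and RD29A were smaller in dxo1 by 2.4 ± 0.25, 2.15 ± 0.31 and 0.95 ± 0.23 on the log2 scale, and the interaction of DFR was -3.92 ± 0.40. ABI5, a transcription factor of ABA signalling, and ADH1 had interactions of -2.30 ± 0.28 and -2.04 ± 0.28, OLEO2 -4.19 ± 0.72, PYL6 -2.24 ± 0.28 and AT4G36700, a seed storage-like gene, -6.23 ± 0.64. In the other direction stood WRKY33 at 2.38 ± 0.22, WRKY40 at 2.80 ± 0.45, CBP60g, a regulator of salicylate synthesis, at 2.35 ± 0.39, LOX4 at 1.58 ± 0.25, AT5G51190 at 3.67 ± 0.41 and the mitochondrial carrier DIC2 at 3.22 ± 0.23. WRKY33 went from 114 ± 1.09 to 55.7 ± 7.34 CPM in Col-0 and from 114 ± 7.93 to 316 ± 11.6 in dxo1 (SD, n = 2). COR15A (-0.47 ± 0.25, adjusted p = 0.267) and HAI1 (0.06 ± 0.59, adjusted p = 0.968) did not pass.

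The interaction was called for 836 genes upward and 917 downward of 19644. Of these 1753 genes, 1513 had the larger response in Col-0 and 240 in dxo1, and in 1053 the fitted responses of the genotypes had opposite signs. Over all genes the SD of the log2 response was 1.2 in Col-0 and 0.79 in dxo1. Flavonoid genes had 9 of 11 lower with a median interaction of -1.85 (adjusted p = 2.33e-09, adjusted p = 0.0499 with an estimated correlation), and seed storage genes 1 of 10, 7 adjusted over the list alone, with a median of -1.78, or -1.4 with members at their bound (adjusted p = 1.3e-06, adjusted p = 0.0765 with an estimated correlation). ABA-induced genes had 4 of 32 higher and 11 lower (median -0.48, adjusted p = 0.0107, adjusted p = 0.456 with an estimated correlation). Plastid transcription genes had 3 of 16 higher, 6 adjusted over the list alone (median 0.44, adjusted p = 0.00452, adjusted p = 0.146 with an estimated correlation). The other lists did not pass. Scaling by library size alone shifted the median gene to 0.11, and this scaling gave 1188 higher and 720 lower. The count was 832 and 813 without Col-0 NT GMUCT replicate 1 and 2. Leaving out single libraries ended the calls of RD29A in 3 fits. In simulated data interactions of log2 1 were recovered at 44.8% and of log2 2 at 98.5%.

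A family of 5 correlations of fitted changes across genes was used as a description, since genes are not independent replicates. ABA responses of Col-0 and dxo1 correlated at r = 0.484 (rho 0.298) over 4965 genes in total RNA and at r = 0.70 (rho 0.346) over 19644 genes in GMUCT libraries. For NAD enrichment r was 0.0804 (rho 0.0852) over 5475 genes, and 0.142 for genes with a mean of at least 10 CPM. Changes in NAD enrichment and in GMUCT over total RNA correlated across 5469 genes at r = 0.449 (rho 0.478) for ABA in Col-0 and r = 0.548 (rho 0.555) for dxo1 in NT. These pairs share their total RNA libraries, which were not split between them, since each part would hold 1 library per group. Simulations with no change other than sampling gave r of 0.650 (0.634 to 0.670) and 0.617 (0.597 to 0.631). The observed covariances were 0.651 and 0.665 against simulated ones of 0.484 and 0.444. The total RNA value fell to 0.315 without Col-0 NT total RNA replicate 1. The NAD value was 0.0162 without Col-0 ABA NAD replicate 2, 0.0366 without Col-0 NT total RNA replicate 1, 0.0395 without dxo1 NT total RNA replicate 2, 0.0400 without dxo1 NT NAD replicate 1, 0.0452 without dxo1 ABA total RNA replicate 2 and 0.0485 without Col-0 NT NAD replicate 2. The Col-0 ABA value of NAD and GMUCT was 0.245 without Col-0 ABA NAD replicate 2 and 0.694 without Col-0 NT total RNA replicate 1.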

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

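Tests chosen only after the result was seen were the overlap with small RNA genes, the removal of organelle and non-coding genes, the library-size value of the interaction and the seed gene test, and the GMUCT comparisons behind the pattern of smaller ABA responses were themselves added after the depths were seen. The results given first are here because the test of the difference between the ABA responses of Col-0 and dxo1 passed.

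In GMUCT libraries the log2 interaction was -2.40 for RAB18, -2.15 for RD29B, -0.95 for RD29A, -2.30 for ABI5 and -2.04 for ADH1. Anthocyanin genes stood at -3.92 (DFR), -1.85 (CHS) and -2.50 (UGT75C1), and seed genes at -4.19 (OLEO2) and -6.23 (AT4G36700). The receptors PYL6 and PYR1 had -2.24 and -0.77. AOC2 of jasmonate synthesis had -1.56, the chaperone HSP70-4 -1.02, CHLD of chlorophyll synthesis -1.14 and the antenna gene LHCB1.2 -1.10. Positive values were found for WRKY33 (2.38), WRKY40 (2.80), CBP60g (2.35), LOX4 (1.58), SIG5 (1.74), SIG4 (0.91), PTAC12 (0.81), the Casparian strip genes CASP1 (1.82) and CASP2 (1.45), the phosphate transporter PHT1;1 (1.73), DIC2 (3.22), AT5G51190 (3.67) and ABA1 (0.80). Single libraries decided some calls: those of ABA1, CASP1, HSP70-4, LHCB1.2, PTAC12, PYR1, RD29A and SIG4 were lost in at least 1 fit without a library. By list, camera adjusted p were 2.33e-09 for flavonoid, 1.3e-06 for seed storage, 0.00452 for plastid transcription and 0.0107 for ABA-induced genes, of which flavonoid alone passed with an estimated correlation. For GMUCT over total RNA, AT1G64490 had -4.21. In total RNA the seed storage, small RNA pathway and chloroplast lists had adjusted p of 1.04e-05, 0.00383 and 0.0113, and for NAD enrichment the chloroplast and mitochondrial lists had 0.00764 and 0.00722, none of which passed with an estimated correlation.

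A first pattern is the 25 protein-coding genes lower in NAD than in total RNA in all 4 conditions. Of these 60% overlap an annotated small RNA gene on either strand, against 0.442% of genes never called lower (one-sided Fisher's exact p = 1.52e-27), so reads of small RNAs may account for these genes. That 10 of the 25, among them FD3 and AT4G15030, overlap no annotated one argues against it as the source for all. Removing a length trend left 96.8% of the median, but the same values chose the genes. Length, unannotated small RNAs, lack of a 5' NAD cap and losses in capture stay open for the 10.

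A second pattern is the higher level of nuclear photosystem transcripts in NAD libraries. Their median exceeded 98.1% or more of 10000 lists matched on length and expression in each condition, which argues against a length trend as the whole cause. Without organelle genes the median over the conditions kept 88.7%, and with nuclear protein-coding genes alone each condition at least 78.4%. Both fits kept TMM scaling, while library-size scaling turned the Col-0 ABA median to -0.40, so a few abundant genes stay open. The list did not pass with an estimated correlation in any condition. NAD caps and unspecific binding in capture both could give this pattern, and no mock capture was analysed here to tell them apart.

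A further pattern is the smaller ABA response of ABA-induced, flavonoid and seed storage genes in dxo1 GMUCT libraries, with a median interaction of -1.06 over 53 members (-0.48, -1.85 and -1.78 by list, with 4 of 32 ABA-induced genes higher and 11 lower and 1 of 10 seed storage genes lower), of which ABA-induced and seed storage genes did not pass with an estimated correlation (adjusted p = 0.456 and 0.0765). Flavonoid genes had a median of 0.93 in dxo1 NT (5 of 11 higher, 1 lower) and -0.94 with ABA, neither passing with an estimated correlation (adjusted p = 0.296 and 0.0549), so a baseline difference stays open. The pooled median was -0.94 with library-size scaling, which argues against scaling. Thinning to equal depth kept 90.9%, with 4794 ABA calls in Col-0 and 1227 in dxo1, which argues against unequal depth. CRU2 (1 count in dxo1 ABA), ABI3, SESA1, SESA2 and SESA5 departed by over 3 SE from the seed list median. This argues against a smaller share of otherwise equal seed tissue. A difference between the genotypes in ABA signalling, decapping or cleavage, growth stage or hormone uptake stays open and was not tested.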

How the results depend on the processing

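The nuclear protein-coding alternative and all tests of GMUCT libraries alone were chosen after seeing the data. No gene, list test or correlation that passed came out in the opposite direction of its test. List medians did change sign with library-size scaling. Among lists that had passed, these were photosystem genes for NAD against total RNA in Col-0 ABA (0.53 to -0.40), chloroplast (-0.29 to 0.75) and mitochondrial genes (-0.77 to 0.35) for the interaction on NAD enrichment, seed storage genes for GMUCT over total RNA with ABA in Col-0 (-1.13 to 0.95) and ABA-induced genes in dxo1 NT GMUCT libraries (-0.14 to 0.01). Among gene results 2072 of 2204 kept their direction and side of the threshold under alternatives other than leaving out a library, 117 no longer passed, 12 newly passed and 3 changed sign without passing. Of 1368 gene results without 1 library, 1097 kept both, 259 no longer passed, 5 newly passed and 7 changed sign without passing. List tests were not run without 1 library. Of 1732 list results 1497 kept both, 175 no longer passed, 25 newly passed and 35 changed direction without passing. Of 198 counts 129 stayed within 1.5 times the value reported, as did 62 of 160 without 1 library. Total counts for GMUCT libraries alone stayed within 1.5 times under every alternative other than leaving out a library, but library-size scaling moved the higher and the lower count of dxo1 in NT and in ABA by more. In each sentence below values follow the order named, and the cause was not tested unless it is stated.

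With the DESeq2 Wald test, GMUCT over total RNA gave 387 for ABA in Col-0, 99 for ABA in dxo1, 130 for dxo1 in NT, 347 for dxo1 in ABA and 47 for the interaction. NAD enrichment gave 11 for ABA in Col-0 and 39 for dxo1 in NT, and total RNA 34 for dxo1 in NT and 4 in ABA. With DESeq2 size factors in edgeR there were 14 for GMUCT over total RNA and 1 for NAD enrichment with ABA in dxo1, and 0 for total RNA of dxo1 in NT. Library-size scaling gave 29, 16, 13 and 14 for GMUCT over total RNA in the first 4 of these contrasts, 4 and 0 for NAD enrichment with ABA in dxo1 and of dxo1 in NT, and 8 and 0 for total RNA of dxo1 in NT and in ABA. NAD against total RNA gave 76 in Col-0 NT, 383 in Col-0 ABA, 98 in dxo1 NT and 40 in dxo1 ABA with that scaling.

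Without a low-count filter, which tests more genes, GMUCT over total RNA gave 205 for ABA in Col-0, 62 for ABA in dxo1, 124 for dxo1 in NT, 205 for dxo1 in ABA and 13 for the interaction. NAD enrichment gave 6, 25 and 33 for the first 3 of these and 2 for the interaction, and total RNA 61, 107, 128, 54 and 8 for all 5. With nuclear protein-coding genes alone GMUCT over total RNA gave 15 for ABA in dxo1, 63 for dxo1 in NT and 4 for the interaction, NAD enrichment 1, 0 and 4 for ABA in Col-0, ABA in dxo1 and dxo1 in NT, and total RNA 1 for dxo1 in NT. Without organelle genes ABA in dxo1 gave 13 for GMUCT over total RNA, 1 for NAD enrichment and 23 for total RNA, and dxo1 in NT gave 0 for total RNA. For genes with a mean of at least 10 CPM the correlation of ABA changes was 0.142 for NAD enrichment and 0.792 for GMUCT libraries.

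A fit of the groups in the contrast alone, which has fewer libraries, gave 569 for ABA in Col-0, 0 for ABA in dxo1, 180 for dxo1 in NT and 46 for dxo1 in ABA with GMUCT over total RNA, where edgeR with all groups gave 112, 25, 34 and 101. It gave 1, 1 and 0 for NAD enrichment in the first 3 of these, 265, 1, 0 and 0 for total RNA, and 37 and 153 for NAD against total RNA in Col-0 ABA and dxo1 ABA. With a replicate block, which assumes that equal replicate numbers form a pair, GMUCT over total RNA gave 39 for ABA in dxo1 and 60 for dxo1 in NT, NAD enrichment 12 for dxo1 in NT, and total RNA 47, 97, 82 and 22 in the 4 contrasts. The labels do not state such pairing. In total RNA the differences between replicates 1 and 2 correlated across genes at r = 0.235 for Col-0 NT with dxo1 NT, 0.190 for Col-0 NT with dxo1 ABA and 0.266 for dxo1 NT with dxo1 ABA, and at 0.0243 to 0.0410 for pairs with Col-0 ABA, so a link between replicate numbers stays open there.

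Leaving out 1 library leaves a group with 1, which is then assumed to vary like the other groups. The ranges were 4 to 16, 4 to 214, 0 to 65, 0 to 360 and 0 to 10 for total RNA with ABA in Col-0, ABA in dxo1, dxo1 in NT, dxo1 in ABA and the interaction. In the same order they were 0 to 10, 1 to 25, 0 to 78, 0 to 8 and 0 to 32 for NAD enrichment, and 7 to 99, 3 to 168, 0 to 77, 7 to 541 and 0 to 59 for GMUCT over total RNA. GMUCT libraries alone gave 2963 to 4134, 1021 to 1509, 1359 to 2876, 4171 to 5005 and 813 to 1837. NAD against total RNA gave 91 to 116 in Col-0 NT, 43 to 95 in Col-0 ABA, 263 to 348 in dxo1 NT and 114 to 1042 in dxo1 ABA. Correlations of ABA responses ranged from 0.315 to 0.474 in total RNA, 0.0162 to 0.101 in NAD enrichment and 0.635 to 0.694 in GMUCT libraries. Those of NAD enrichment with GMUCT over total RNA ranged from 0.245 to 0.694 for ABA in Col-0 and from 0.418 to 0.742 for dxo1 in NT.

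In simulated data a change of log2 1 was recovered at 0% for NAD enrichment and GMUCT over total RNA with ABA in Col-0, at 3.23% for total RNA with ABA in Col-0, at 10.2% for NAD against total RNA in Col-0 NT and at 85.1% for ABA in Col-0 GMUCT libraries. Depth and the spread between replicates were not separated as limits.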

Other observations

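These genes were chosen after their values were seen. ICL, the glyoxylate-cycle enzyme that lets seedlings live on stored oil, went from 22.0 ± 1.36 to 13739 ± 415 CPM with ABA in Col-0 GMUCT libraries, and from 33.9 ± 4.77 to 1353 ± 68.5 in dxo1 (SD, n = 2). SESA1, a seed albumin, had a log2 difference of -0.18 ± 0.23 between dxo1 ABA and Col-0 ABA in GMUCT libraries (adjusted p = 0.59), while the cruciferin CRU2 had 1 count in dxo1 ABA against 176 in Col-0 ABA. BHLH100, which regulates iron uptake, had 0.836 ± 0.342, 0.0778 ± 0.110, 2.64 ± 0.184 and 11.9 ± 1.24 CPM in Col-0 NT, Col-0 ABA, dxo1 NT and dxo1 ABA.

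JAZ7, a jasmonate repressor, had 2.03 ± 0.126 CPM in dxo1 NT and 3.62 ± 0.380 in dxo1 ABA, against 0.0963 ± 0.0162 and 0.242 ± 0.0979 in Col-0.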
